A study of Bos taurus with 16 samples.

How the data were processed

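Whole blood from 16 dairy cattle was profiled by RNA sequencing. Per the labels, 8 animals had a high and 8 a low milk protein yield, and each library came from its own numbered sample. The design text of the series names the groups by another trait, written only as an abbreviation, while the title and the label of every sample name milk protein yield. The grouping used here follows the sample labels. Per the labels' protocols, blood was frozen in liquid nitrogen, total RNA was extracted with Trizol, and libraries were made with the NEBNext Ultra RNA kit for Illumina sequencers. No label gives a sequencing batch, a sampling date, a sire, a lactation stage or a blood cell count.

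The deposited values are raw counts of reads per Ensembl gene identifier, with no normalization by the authors. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools 1.4 and HTSeq were used, with the bovine assembly UMD3.1. The HTSeq version, its strand setting and the annotation release are not given in the sources used here. Each file held 24616 gene identifiers and 5 further entries for alignments that were given to no gene. Of all alignments that the files tally, 18.3% to 23.6% per library lay in no gene, 0.556% to 0.887% overlapped more than 1 gene, and 4.0% to 8.81% were not unique. These entries were kept out of library totals and tests. Because non-unique alignments were set aside, genes with near-identical copies are counted low, and without a stated strand setting reads of a gene and an antisense neighbour cannot be told apart.

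The deposited files do not pair identifiers with gene names. The name table at hand, for a later bovine assembly (ARS-UCD2.0), lists 37063 genes, none of them with an Ensembl identifier, and 0 of the 24616 identifiers matched. Genes are therefore given by identifier, at most 2 in each direction. For the same reason the 39 gene lists fixed in advance (pathways, blood cell types and other tissues) could not be scored, and neither could the shares of erythroid, mitochondrial and ribosomal protein transcripts. Blood cell composition was thus not measured. GC content and gene length were also not at hand for any identifier, so checks of these are void.

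Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filter filterByExpr (minimum count 10, minimum total 15), milk protein yield group as the factor and Benjamini-Hochberg adjustment. Log2 fold changes are high minus low yield. A gene was called at an adjusted p below 0.05. Confidence intervals cover 95%. Levels are CPM, counts scaled to a TMM-adjusted library total of 1000000, and the spread given is the SD between animals. For the genes printed, the group difference in log2(CPM + 1) was also tested with an exact two-sided permutation test over all splits of the animals, whose smallest possible p is 0.0001554. Library measures were tested in the same way, with Benjamini-Hochberg adjustment over the 3 planned measures and, separately, over those added later. The genes to be named were fixed by rule: those called with the largest changes at a mean CPM of at least 1, filled up to 20 by smallest p. The printed identifiers are the 2 with the smallest p in each direction among these 20. The rule's further parts, which start from gene symbols, could not be applied.

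Alternatives were other scalings, other filters on low counts, robust dispersion, DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), the replicate number as a block, 1 surrogate variable from sva 3.50.0, other thresholds, and leaving out each of the 16 libraries in turn. Libraries were compared in all 120 pairs by a chi-square of their counts. The lowest chi-square per degree of freedom was 31.7, so no pair agreed within sampling noise, as a library deposited again would, and all 16 were kept. That they came from separate animals rests on the labels.

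Totals over genes ran from 23727368 to 39793845 counts per library, with a median of 31342690. The edgeR test was tested on simulated data made from the 13159 tested genes, each drawn independently of the others, with 200 genes changed. At an adjusted p below 0.05 it recovered 10.2% of 1.5-fold, 38.0% of 2-fold, 90.0% of 4-fold and 98.0% of 8-fold changes, and 3 of its 120 calls were unchanged genes. The biological coefficient of variation was 0.410 and the median SE of a log2 fold change 0.242.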

Results

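The transcriptome of whole blood was compared between 8 dairy cattle with high and 8 with low milk protein yield, to find genes whose transcript level in blood differed with this trait. Whole blood is a mixture of red cells, platelets and several kinds of white cell, and the counts are sums over all of them. Each animal gave 1 library, and the animal is the replicate throughout.

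The totals ran from 23727368 to 39793845 counts in genes per library. The mean was 32126931 ± 4184634 counts in the high-yield animals and 29811406 ± 4691094 in the low-yield animals (SD, n = 8 each, exact permutation p = 0.311, adjusted p = 0.934). A library held 15534.6 ± 1357 genes with a count in the high-yield group and 15810 ± 154 in the low-yield group (SD, n = 8, exact permutation p = 0.988). The 10 most abundant genes took 6.98% ± 0.963 and 6.88% ± 0.654 of the counts (SD, n = 8, exact permutation p = 0.825). No difference passed its exact test with all 16 libraries, but the sign of 2 of them changed when a library was left out. Without high-yield animal 4 the high-yield animals had 201 more genes with a count on average (adjusted p = 0.0783 from exact permutation), more than the low-yield SD of 154. The difference in the share of the 10 most abundant genes, high minus low, was -0.168 percentage points without it (adjusted p = 0.620 from exact permutation) and -0.071 without low-yield animal 3.

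The library of high-yield animal 4 stood apart from the other 15. It held 12197 genes with a count, against 15494 to 16217 in the others, at a total of 31191847 counts. Genes with 1 to 10 counts made up 3.07% of its detected genes, against 16.9% to 19.0% elsewhere. Its counts correlated with those of other libraries at a Spearman coefficient across genes of 0.798 to 0.869, while the other libraries correlated with each other at 0.931 to 0.990. Its genes at 21 to 35 counts numbered 826, against 598 to 683 in the other libraries. The count of genes that differed between the groups is therefore also given without it.

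**Figure D1:**
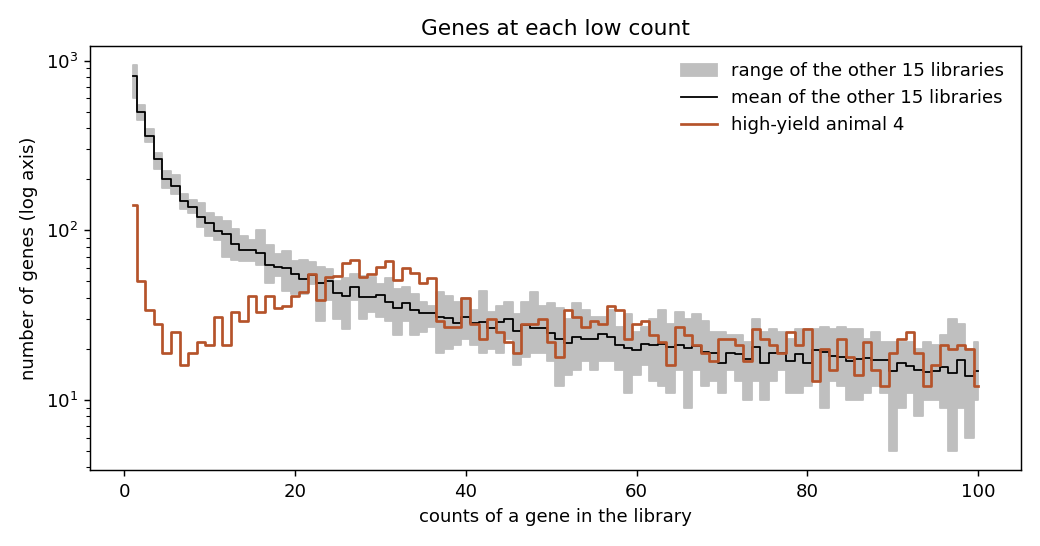
Number of genes (log axis) at each count from 1 to 100 in the library of high-yield animal 4 (orange line), with the mean (black line) and range (grey) of the other 15 libraries. High-yield animal 4 has 374 genes at 1 to 10 counts, against 2652 to 3051 in the others, and more genes than the others at about 29 counts.

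**Figure D2:**
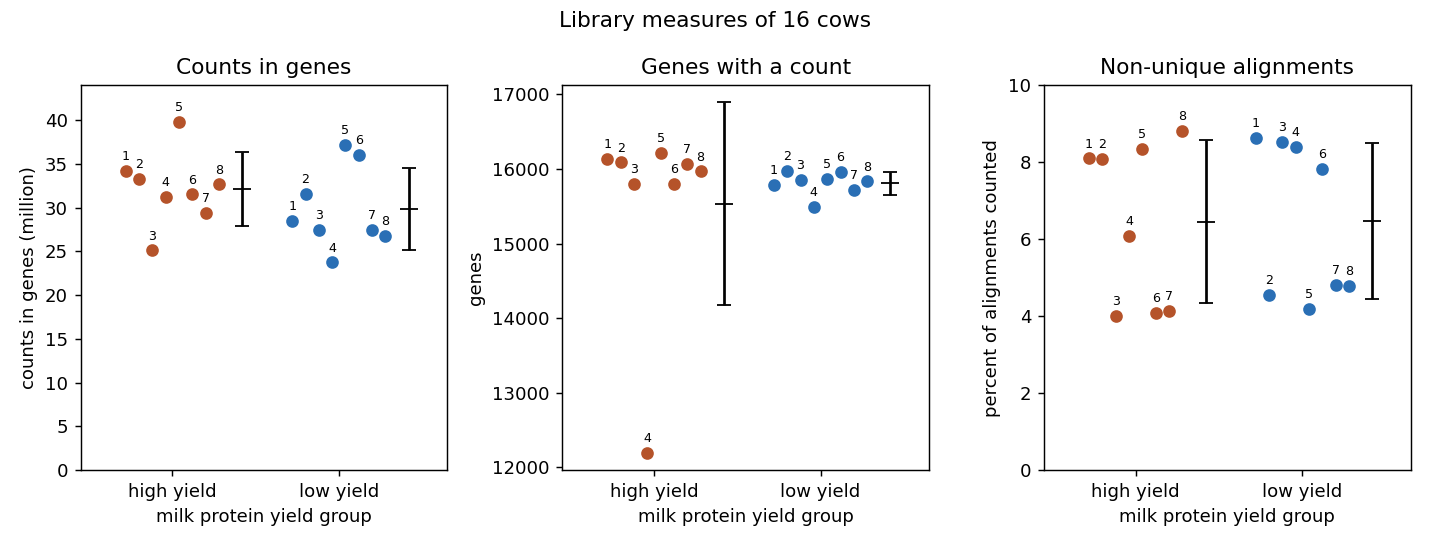
Total counts in genes, number of genes with at least 1 count, and non-unique alignments as a percent of all alignments tallied, for each of the 16 animals by milk protein yield group. Points are animals with their replicate number, and bars are the group mean ± SD (n = 8). The axis of the gene number does not start at 0. High-yield animal 4 has 12197 genes, below the 15494 to 16217 of the others, and the non-unique share falls into 8 libraries at 7.83% to 8.81% and 7 at 4.0% to 4.81%, with both groups in each.

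No gene differed between high-yield and low-yield animals at an adjusted p below 0.05 in edgeR's quasi-likelihood test, and none at an adjusted p below 0.10. Of the 24616 identifiers in the files, 18900 had a count and 13159 passed the filter and were tested. These held 99.96% of the gene counts. At an unadjusted p below 0.05 there were 335 genes, 244 higher and 91 lower in the high-yield animals. This is 2.55% of the genes tested. Uniform p-values would give 5%, or 658 genes, while other splits of the same 16 animals gave a median of 358. The count moved widely with single animals, to 1010 without high-yield animal 7 and 177 without low-yield animal 8. It was 553, 221 and 186 without low-yield animal 2, low-yield animal 6 and high-yield animal 5. Of the 335, 100 also had a log2 fold change of at least 1 in size. DESeq2 called 3 genes, with 600 at an unadjusted p below 0.05, and limma voom with sample quality weights called 2, with 3586. Without high-yield animal 4, edgeR called 0 genes and 507 were below an unadjusted p of 0.05, 187 of them among the 335, and 285 were higher and 222 lower. The excess of higher over lower genes thus depended on this animal and on the scaling. With all 16 libraries 72.8% of the genes at an unadjusted p below 0.05 were higher with TMM factors, 76.6% with DESeq2 size factors, 79.8% with upper-quartile factors and 56.1% with library totals alone. It was 56.2% without high-yield animal 4 and 47.3% with 1 surrogate variable as a covariate. That variable was 0.960 in high-yield animal 4 and -0.156 to -0.0166 in the others. It thus mainly marked this animal, so both settings are much alike.

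The gene with the smallest p, ENSBTAG00000005034, averaged 12.1 ± 8.62 CPM in the high-yield and 1.16 ± 0.505 CPM in the low-yield animals (SD, n = 8 each). The log2 fold change was 3.38 (SE 0.549, 95% confidence interval 2.23 to 4.54), a 10.4-fold difference with an interval of 4.69 to 23.2. The unadjusted p was 8.39e-06, and the adjusted p from edgeR was 0.110, above the threshold. An exact permutation test of this gene alone gave p = 0.00155 (n = 8). In the high-yield group 7 of the 8 animals lay above the highest low-yield animal, which had 1.75 CPM. High-yield animal 3, at 0.932 CPM, lay within the low-yield range of 0.418 to 1.75 CPM, and high-yield animal 1, at 2.25 CPM, lay just above it. The adjusted p in edgeR fell to 0.00574 without animal 3 and to 0.0327 without animal 1, and lay between 0.154 and 0.411 when any other library was left out. DESeq2 gave an adjusted p of 7.07e-08 for this gene, and adjusted p over all settings tried ran from 6.69e-08 to 1.

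ENSBTAG00000013274 was the gene with the next smallest p. It averaged 16.2 ± 5.06 CPM in high-yield and 8.92 ± 1.29 CPM in low-yield animals (SD, n = 8 each), a log2 fold change of 0.86 (SE 0.181, interval 0.48 to 1.24). All 8 high-yield animals, at 11.2 to 26.3 CPM, lay above all 8 low-yield animals, at 7.32 to 10.8 CPM. The highest was high-yield animal 4, and without it the log2 fold change of this gene was 0.72. The exact permutation p for this gene alone was 0.0001554, the smallest that 8 against 8 animals can give, while its adjusted p in edgeR was 0.986. DESeq2 gave an adjusted p of 0.0126, within a range of 0.00574 to 1 over the settings tried. It was the only tested gene whose groups did not overlap in this way, and chance alone gives 0.01554% of genes, or 2.04 genes.

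Among genes lower in high-yield animals, ENSBTAG00000034918 had the smallest p. It averaged 83.8 ± 28.5 CPM in high-yield and 161 ± 68.6 CPM in low-yield animals (SD, n = 8 each). The log2 fold change was -0.94 (SE 0.263, interval -1.50 to -0.39), and 5 of the 8 low-yield animals lay above the highest high-yield animal. ENSBTAG00000048306 followed, with 1.52 ± 0.240 CPM in high-yield and 2.45 ± 0.63 CPM in low-yield animals (SD, n = 8 each). Its log2 fold change was -0.68 (SE 0.206, interval -1.12 to -0.25), and 7 of the 8 low-yield animals lay above the highest high-yield animal. The adjusted p of both genes in edgeR was 0.986. High-yield animal 4 had the lowest level of both genes, and without it their log2 fold changes were -0.83 and -0.64. Exact permutation tests of each gene alone gave p = 0.0028 for the former and p = 0.000311 for the latter (n = 8). These tests stand outside the adjustment for the 13159 genes from which the genes were picked.

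**Figure D3:**
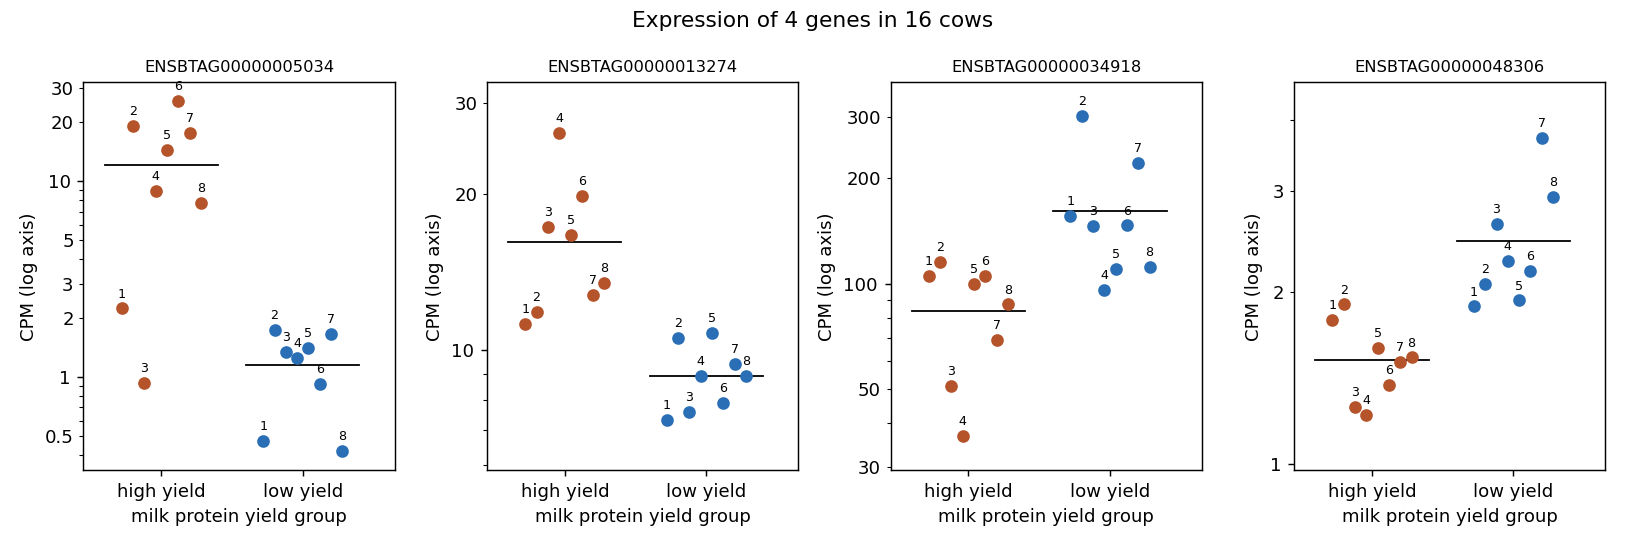
Levels of 4 genes in CPM (counts scaled to a library total of 1000000, log axis) in the 16 animals by milk protein yield group, with replicate numbers beside the points and horizontal lines at the group means (n = 8). For ENSBTAG00000005034, 7 of 8 high-yield animals lie above the highest low-yield animal, and for ENSBTAG00000013274 all 8 do, while the adjusted p from edgeR was 0.110 and 0.986.

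The 20 genes with the smallest p at a mean of at least 1 CPM held 16 that were higher and 4 that were lower in the high-yield animals. Their log2 fold changes were 0.46 to 5.25 in size and their unadjusted p at most 0.00622. High-yield animal 4 had the highest level of the 16 animals in 6 of these genes and the lowest in 2. Without this animal all 20 had the same direction and 19 were still at an unadjusted p below 0.05. The 20 were picked for their small p with the other 15 libraries included, so this was largely fixed by the choice. Of all 335 genes at an unadjusted p below 0.05 in edgeR, 187 remained so without this animal.

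The libraries also fell into 2 sets by their share of non-unique alignments, apart from high-yield animal 4 at 6.08%. The set with the higher share held 4 high-yield and 4 low-yield animals, and the set with the lower share 3 and 4. The mean share was 6.45% ± 2.12 in the high-yield and 6.46% ± 2.03 in the low-yield group (SD, n = 8, exact permutation p = 0.994). The log2 fold change of ENSBTAG00000005034 was 3.41 within the higher set and 3.54 within the lower set, and that of ENSBTAG00000013274 was 0.72 and 0.79. For ENSBTAG00000034918 the values were -0.45 and -1.26, and for ENSBTAG00000048306 they were -0.42 and -0.89. No gene passed an adjusted p of 0.05 in edgeR within either set. At an adjusted p below 0.10 edgeR gave 121 genes in the higher set, 56 of them higher in high-yield animals (smallest adjusted p 0.0537), and 0 in the lower set. Of the 35 splits of the 8 libraries of the higher set, the real one included, 2 gave at least 121 genes, and the other of them gave 1950. At an unadjusted p below 0.05 there were 2203 genes in the 8 libraries of the higher set and 276 in the 7 of the lower set. Of the 2203, 863 were higher and 1340 lower in the high-yield animals, and of the 276, 116 were higher and 160 lower. Of the 2203, 2184 were also tested in the lower set, and 727 had the same direction there. Of the 276, 269 were also tested in the higher set, and 90 had the same direction there. These counts of shared direction were not set against other splits.

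The precision sets what a count of 0 called genes can exclude. For 72.7% of the tested genes the 95% confidence interval of the log2 fold change lay within -1 to 1, and for 84.2% without high-yield animal 4. In simulated data of this design 38.0% of 2-fold changes were recovered with all 16 libraries and 54.2% without that animal. These were 19 of 50 and 26 of 48 changed genes, from 1 draw each. Of 1.5-fold changes, 10.2% and 18.4% were recovered, so most differences of that size in a gene would be missed at this number of animals. The simulation drew genes independently and held no library like that of high-yield animal 4. It also changed 200 genes at once, and many calls ease the Benjamini-Hochberg cut, which is stricter for a gene changed alone. With all 16 libraries 4.64% of its unchanged genes were at an unadjusted p below 0.05 in edgeR, against 2.55% of genes in the real comparison. The shares recovered may therefore overstate what the real test would find.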

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

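The tests in this part were chosen after the results they bear on had been seen. Of 28 comparisons of the highest or lowest animal with the rest of its group, 3 showed an animal far from the others, and chance gives about 5% of them. All 3 concern high-yield animal 4: its number of genes with a count (12197, others of its group 15800 to 16217), its share of detected genes at 1 to 10 counts (3.07%, others 17.5% to 19.0%), and its score on the first principal component (227, others -38.4 to -5.91). That component carried 53.5% of the variance and its difference between groups had an exact permutation p of 0.729.

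Genes at a few counts were scarce in high-yield animal 4, and genes at about 29 counts were in excess: 826 genes had 21 to 35 counts, against 598 to 683 in the other libraries. Shallow sequencing is argued against, since its total of 31191847 counts lay within the range of the others, 23727368 to 39793845. A candidate explanation, drawn from these values, is that the library came from few starting molecules, each read many times over, and genes with 2 such molecules would then stand at about double the peak: 406 genes had 51 to 65 counts, against 286 to 376 in the other libraries. It leaves part of the pattern open: among genes at which 100 to 200 counts were predicted from the other animals, 15.5% had no count at all, where molecules read 29 times each would leave 1.04%, and the spread of reads per molecule was not measured. Uneven loss of transcripts and another cell composition in this animal cannot be told apart for these genes, as no cell type could be scored.

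The split of the libraries by their share of non-unique alignments did not follow milk protein yield, since each set held both groups and the group means differed by less than the spread (exact permutation p = 0.994). Depth is argued against as well: 7 of the 7 libraries with the lower share had totals within the range of the 8 with the higher share. An unrecorded batch that reached the gene counts may lie behind it, but no label names one. In a model with the yield group and without high-yield animal 4, the set gave 2123 genes at an unadjusted p below 0.05, or 16.01% of those tested, and 0 at an adjusted p below 0.05 in edgeR (smallest 0.178). A technical batch and a difference between animals, such as in their cell composition, therefore cannot be told apart for these sets.

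ENSBTAG00000005034 had the smallest p of all genes, and 3 of 100 splits of the 16 animals, the real one included, gave a smallest p as small (real 8.39e-06, lowest of the others 2.78e-06). The exact 95% binomial interval of that share, 0.623% to 8.52%, reaches above 5%, and the gene's adjusted p in edgeR was 0.110, so chance is not excluded. The fold change did not rest on any 1 library, as the lowest log2 fold change with a library left out was 3.13, nor on the sets by non-unique share, within which the lower of both log2 fold changes was 3.41. The gene was picked for its small p in these same libraries, so such refits are no separate support for a group difference. Reads shared with gene copies, a genetic variant against the reference, and a link with milk protein yield beyond these 16 animals stay open, as none of these was tested.

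In edgeR, 0 genes were called in the real comparison. All 100 splits drawn from 6435 must give at least as many, so they say nothing of chance for this count, and the highest of the others called 1327. For the numbers of genes at an unadjusted p below 0.05, chance could not be excluded. At an unadjusted p below 0.05 the real split gave 335 genes and 52 of the 100 splits gave as many, with 3588 as the highest other. Without high-yield animal 4 the real split gave 507 genes and 39 of 100 gave as many, with 3569 as the highest other. Within the 8 libraries of the higher non-unique share the real split gave 2203 genes and 5 of 35 splits gave as many. The highest other gave 3662 and the median of the others was 342, so the real count was among the larger ones there. For the 121 genes of these 8 libraries at an adjusted p below 0.10 in edgeR, 2 of 35 splits gave as many, with 1950 as the highest other. Chance could not be excluded there either. With all 16 libraries and without high-yield animal 4, splits with several times the real count point to a structure of the samples that the yield groups do not follow. How far that structure follows the non-unique share stays open. The 11 splits of all 16 libraries that part the 8 of the higher set at least 6 to 2 had a median of 619 genes, against 358 over all splits but the real one, and the split with the most genes parts them 6 to 2. Without high-yield animal 4 the median of 11 such splits was 399, against 329, and the split with the most genes parts them 5 to 3.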

How the results depend on the processing

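The alternatives below were chosen before the data were examined, except those said to be added. The count of called genes stayed at 0 with the other 3 scalings, both other filters, robust dispersion, 1 surrogate variable, and an adjusted p below 0.10. It was 3 with DESeq2, 2 with limma voom, 335 at an unadjusted p below 0.05, and 100 with a log2 fold change of at least 1 in size as well. Leaving out each library in turn gave 0 to 1 called genes, the 1 being ENSBTAG00000005034 without high-yield animal 1 (adjusted p = 0.0327 in edgeR) or 3 (0.00574). Of the 3 genes from DESeq2, 2 were ENSBTAG00000005034 and ENSBTAG00000013274. The other had 222 and 153 counts in 2 low-yield animals and at most 1 elsewhere, and did not pass the edgeR filter. The 2 genes from limma voom, at an adjusted p of 0.0466, were others again, and that fit gave high-yield animal 4 a weight of 0.0395 and had 3586 genes at an unadjusted p below 0.05. Added after seeing the data, and without high-yield animal 4, DESeq2 called 3, limma voom 0, and edgeR with the non-unique set as a term 0. That fit of limma voom still had 3645 genes at an unadjusted p below 0.05, so their large number did not rest on this animal. Why the tools differ was not tested. The log2 fold changes of the 4 printed genes kept their sign in all 31 refits: 2.92 to 3.56 for ENSBTAG00000005034, 0.66 to 0.92 for ENSBTAG00000013274, -1.26 to -0.45 for ENSBTAG00000034918 and -0.89 to -0.40 for ENSBTAG00000048306. These genes were picked for their small p in the same libraries, so the kept signs were largely fixed by the choice. None of the 3 planned library measures (total count, genes detected, share of the most abundant genes) passed an adjusted p of 0.05 in any of 18 alternatives. The measures added later were not run under alternatives.

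The number of genes at an unadjusted p below 0.05 ran from 177 (without low-yield animal 8) to 1010 (without high-yield animal 7) with 1 library left out, and was 507, 553, 186 and 221 without high-yield animal 4, low-yield animal 2, high-yield animal 5 and low-yield animal 6. It was 744 with no filter, 600 with DESeq2 and 569 with the surrogate variable, which mainly marked high-yield animal 4. The labels state no pairing of animals by replicate number, and the counts showed none across genes. Same-numbered animals deviated together at correlations across genes of -0.449 to 0.221, and 0 of 16 libraries correlated best with their own number. A pairing that left little trace in the counts cannot be excluded this way. With the replicate number as a block, 0 genes were called and 151 were at an unadjusted p below 0.05. A cell composition covariate, the gene list tests and the marker scores, all planned, were not run because no identifier matched a gene name. With all 16 libraries, 38.0% of simulated 2-fold changes were recovered, so differences of that size could be missed, in a design where edgeR called 0 genes and DESeq2 3.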

Other observations

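The tests in this part are hypotheses raised after other results had been seen, and both were set down before their own outcome was known. A few genes stood far higher in some animals than in others, with no animal between. Without high-yield animal 4, 5 of 13264 genes showed a gap of at least 8-fold between an upper set of animals at 5 CPM or more and a lower set, with at least 3 animals on each side, and 6 to 10 of the 15 animals were in the upper set. The rule set no upper limit on the level of the lower set. For each of the 5 genes the upper set held 3 or 4 high-yield and 3 to 6 low-yield animals, and the lower set also held both groups. The gap thus did not separate the yield groups for any of them, while a weaker link with yield stays open. In Fisher's exact test 0 of the 5 genes had a p below 0.05 (smallest p = 0.315, adjusted 1), a count that all 100 random groupings must reach, so the planned comparison with them is void. Inherited differences between animals are an untested alternative for such genes.

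Fold changes within the 2 sets of libraries by non-unique share were inversely related, with a correlation across genes of -0.23. Genes are not independent replicates, so this value was set against other splits within each set. Of 2450 pairs of splits, 35.8% gave a correlation as far from 0, within a range of -0.71 to 0.71. The hypothesis that the yield groups differed in opposite ways in the 2 sets is thus not needed for this value. Correlations of that size between arbitrary splits may reflect axes along which many genes vary together between animals. Without high-yield animal 4 the first principal component carried 34.8% of the variance, with an exact permutation p of 0.332 for the yield groups and 0.0424 for the sets (adjusted 0.0901 over 4 components).

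In high-yield animal 4, 834 genes had no count while each of the other 15 libraries had at least 10. Among genes with a median of at least 20 CPM in the others, 506 were at least 8-fold lower in this animal and 4 at least 8-fold higher, against 0 to 5 and 0 to 2 in the other libraries.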
